A study of Homo sapiens with 15 samples.

How the data were processed

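RNA was measured in 15 libraries of HCC1954, a HER2-positive human breast cancer line, grown as parental cells (Pa, 3 libraries) or recovered from brain as synchronous metastases (S-BM, 4), latent cells (Lat, 4) and metachronous metastases (M-BM, 4). Per the labels, total RNA was taken from cultured cells with an RNeasy kit and libraries were made with TruSeq RNA v2, a kit that does not mark the strand. Reads were aligned with Bowtie 0.12.2 to GRCh38 according to the submitters' notes. The read counter, the gene annotation and the normalization method are not given in the sources used here.

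The deposited signal values are normalized counts, 1 value per gene and library, which the authors scaled to similar totals by a method not stated. S-BM, Lat and M-BM share a table, and Pa stands in a separate one. Each column consisted of whole multiples of a single step, within 0.05 reads, so reads per gene were recovered from the values. Column sums lay between 963150 and 1026297. Recovered reads per library came to 17.55, 20.05, 13.25 and 17.14 M reads in S-BM 1 to 4, 19.5, 18.21, 18.61 and 14.15 M reads in Lat 1 to 4, 20.55, 21.84, 20.75 and 21.08 M reads in M-BM 1 to 4, and 15.51, 16.26 and 18.66 M reads in Pa 1 to 3. A floor of 3 reads gives a value of 0.136 to 0.225, depending on the library; floors cover counting error only. The tables list 19845 names, of which 27 had been turned into dates by a spreadsheet, 2 of these repeating an earlier one. Gene positions were taken from a GRCh38 reference table in which 19071 names had a current symbol. Reads shared by near-identical genes (keratins, histones and metallothioneins among them) leave the levels of such genes uncertain.

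The tests, filter, thresholds, gene lists, rule for named genes and most alternatives were set before the data were examined. S-BM, Lat and M-BM were fitted together with limma 3.58.1 in R 4.3.3 on log2(value + 1) of the values as deposited, with 3 group means, 9 residual degrees of freedom and a variance trend. A gene was tested when its value was at least 10 in at least 4 of the 12 libraries, which kept 9646 genes. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The contrasts were Lat minus S-BM, M-BM minus S-BM and M-BM minus Lat, and a moderated F test covered all 3 groups. A filter at a value of 1, which had been set for FPKM or TPM tables, was run first after the values were seen, and both sets of counts were known when the filter of 10 set for normalized counts was restored; the filter of 1 is kept as an alternative.

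The labels give the groups the same replicate numbers. Residuals of libraries with the same number correlated across genes at −0.272 to 0.319, 4 of 12 pairs above 0.1, and those of other pairs at −0.305 to 0.322, so the numbers were not used to pair libraries and a fit with them as a block is an alternative. The labels do not state whether libraries of a group are separate cultures or animals.

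For gene lists, 44 were written with 1118 entries, of which 1067 matched a name in the tables, and 37 had at least 5 tested members. They covered HER2 and ERBB signalling, glycolysis, hypoxia, pentose phosphate, glutamine and glutathione, NRF2, the tricarboxylic acid cycle, oxidative phosphorylation, fatty acid and cholesterol metabolism, mitochondrial dynamics, stress responses, proliferation, MYC, epithelial and mesenchymal state, TGF-beta, WNT, YAP, NOTCH, latency, metastasis mediators, interferon, antigen presentation, NK-cell ligands, cytokines, proteases, S100 proteins, brain cell markers, ribosomal proteins, heat shock, metallothioneins and histones. No entry of a list of mitochondrially encoded genes matched a name in the tables, so these were not analysed here. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. Members were counted over all genes tested and adjusted over the list alone.

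Genes were named by a rule. For each contrast it took the 8 largest called changes per direction among genes whose groups did not overlap and whose mean in the higher group reached the median over tested genes, 49.07. It added up to 3 called members of each called list and a fixed set of 14 genes. As the rule allows for space, up to 6 per direction and up to 2 per list are printed; some genes that the rule named are not reported here. FADS1, SCD, AXL, FN1, KLF13, ACTG2, COL15A1, GALNT6, MGME1, POLR3F and the genes of the parental comparison were chosen after their values were seen.

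Overlap between the comparisons that share S-BM was set beside 100 simulations, in which all 12 libraries were drawn around the S-BM means with no difference between groups, and beside the 6 ways of giving each comparison its own S-BM libraries. Pa values were multiplied by 1.0062, the median ratio over shared genes, and compared as levels only. A gene counted when all Pa libraries lay at least 4-fold outside the range of the 12 others.

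Alternatives were pseudocounts of 0.25 and 8, no filter and filters at 100 and 1, TMM rescaling, quantile normalization, a fit of only the 2 groups compared, robust variance, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the replicate block and leaving out each library in turn. Leaving out S-BM 3 and S-BM 4 together and the filter at 1 were added after the data were seen. The tests were also tested on simulated data, negative binomial libraries drawn around group means with known changes added to some genes. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.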

Results

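Messenger RNA was profiled in HCC1954, a HER2-positive human breast cancer cell line, and in cells of that line taken from brain. The 15 libraries fell into 4 groups: the parental line (Pa, 3 libraries), cells from synchronous brain metastases (S-BM, 4), latent or residual brain-tropic cells (Lat, 4) and cells from metachronous brain metastases (M-BM, 4). All cells had been cultured before RNA extraction. Reads assigned to genes, recovered from the deposited normalized values, ranged from 13.25 to 21.84 M reads per library in S-BM, Lat and M-BM and from 15.51 to 18.66 M reads in Pa. A count of 3 reads corresponded to a normalized value between 0.136 and 0.225, and such limits cover counting error only. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. No pair of libraries differed by as little as sampling noise. The closest pairs, S-BM 3 with S-BM 4 and Lat 1 with Lat 2, stood at 2.17 and 2.64 times the noise level. Other pairs within S-BM stood at 11.53 (S-BM 1 and S-BM 3) to 23.31 times (S-BM 2 and S-BM 4). If the closest pairs are repeats of 1 culture, the p-values, which count each library as a replicate, are too small. Values are means ± SD with n = 4 unless stated, folds are on the log2(value + 1) scale, and adjusted p-values come from limma unless camera is named.

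The series asks how gene expression differs between the parental line and the brain-derived groups. Lat and M-BM libraries resembled each other and stood apart from S-BM, which resembled Pa. The median correlation of log2 values across 9646 genes was 0.978 between Lat and M-BM, 0.859 between S-BM and Lat, and 0.88 between S-BM and M-BM. Against Pa, it was 0.937 for S-BM, 0.808 for Lat and 0.821 for M-BM, where Pa came from a table of its own; genes are not independent replicates. The first principal component carried 71.6% of the variance. S-BM libraries scored from −52.3 to −41.6 on it, Lat libraries from 26.0 to 32.7, and M-BM libraries from 5.4 (M-BM 4) to 26.1.

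**Figure D1:**
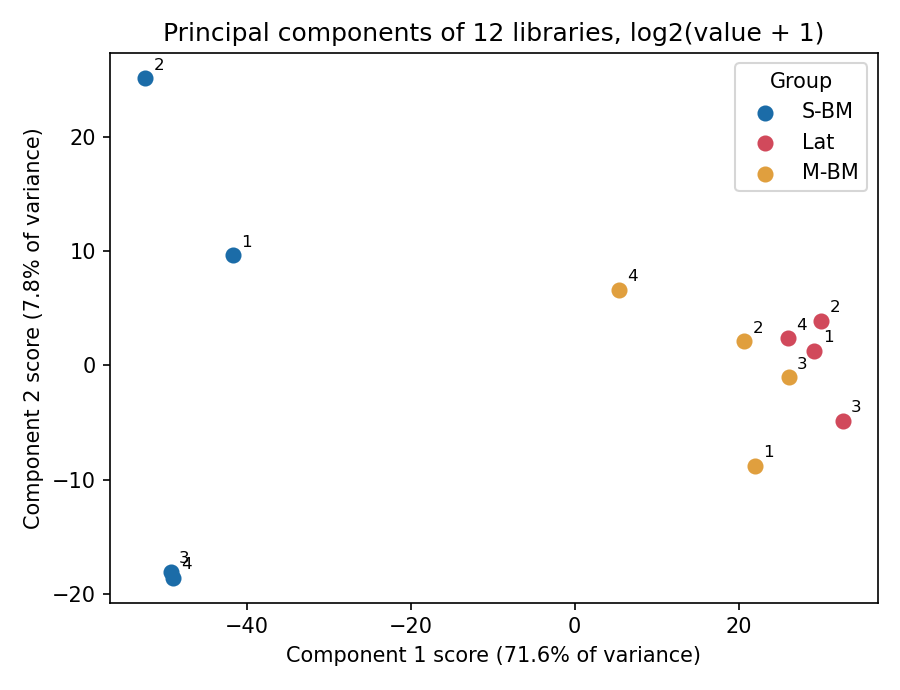
Scores of the 12 S-BM, Lat and M-BM libraries (1 point each, numbered by replicate) on the first (71.6% of variance) and second (7.8%) principal components of log2(value + 1). S-BM lies at negative scores of component 1 and Lat and M-BM at positive ones, with M-BM 4 at 5.4.

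Lat cells against S-BM cells compares cultured cells of the latent group with cultured cells from synchronous metastases. Neither group was measured in the brain. IL24, a cytokine of the interleukin 10 family (chromosome 1, 206897443 to 206904139, GRCh38), rose 81.8-fold, from 2.93 ± 1.71 in S-BM to 304.5 ± 127.5 in Lat (log2 fold change 6.35, SE 0.43, adjusted p = 2.01e-07). FAM129A rose 32.9-fold, the carboxylesterase CES1 29.3-fold, the kainate receptor partner NETO2 20.6-fold and the drug efflux transporter ABCG2 17.2-fold. In the other direction, LMAN1, a cargo receptor between the endoplasmic reticulum and the Golgi (chromosome 18, 59327823 to 59359265), stood at 100.6 ± 12.2 in S-BM and at 0 in all 4 Lat libraries, where 3 reads would give 0.154 to 0.209. The retinoid-responsive gene RARRES1 fell 60.9-fold, from 446.5 ± 50.6 to 7.24 ± 3.67. TNFSF10, which encodes the death ligand TRAIL, fell 42.9-fold, the keratin KRT6A 29.1-fold, ceruloplasmin (CP) 28.7-fold and RARRES3 26.4-fold. Adjusted p-values of these 11 genes ranged up to 4.98e-05, and the 4 Lat libraries did not overlap the 4 S-BM libraries for any of them. KRT6A reads may be split with near-identical keratins, so its level is uncertain. The size of such folds depends on the method where one group is near 0: over the alternatives the log2 fold change ran from 4.77 to 6.80 for IL24, 2.80 to 6.23 for FAM129A, 2.79 to 5.98 for CES1, 3.01 to 4.70 for NETO2, −6.12 to −4.93 for RARRES1 and −5.47 to −3.03 for KRT6A. Without S-BM 3 and S-BM 4, CES1 went from 4.87 to 3.94, NETO2 from 4.36 to 3.57 and KRT6A from −4.86 to −4.07.

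**Figure D2:**
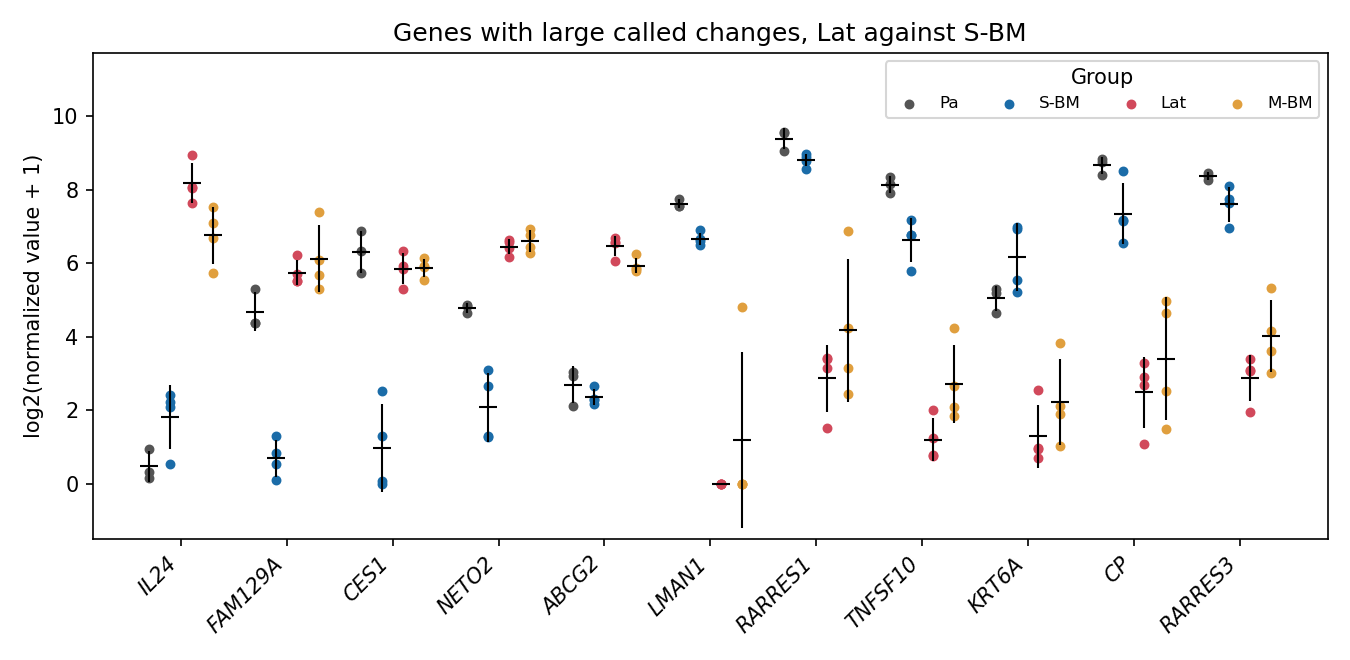
Normalized values on the log2(value + 1) axis for 11 genes with large called changes in Lat against S-BM; each point is a library, bars are the mean ± SD of the log2 values (n = 4, Pa n = 3), and Pa is drawn as deposited in its own table. IL24 lies at 304.5 on average in Lat against 2.93 in S-BM, and LMAN1 at 0 in every Lat library.

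Of 9646 genes tested, 5754 (59.7%) passed an adjusted p of 0.05 in this comparison, 2917 higher and 2837 lower in Lat. At 2-fold or more there were 1294 genes, 555 higher and 739 lower, and at 8-fold or more 87. The libraries of the groups did not overlap for 54.5% of genes, where chance gives 2.86% if all libraries are independent. Leaving out S-BM 3 and S-BM 4 together, a choice made after their values were seen, gave 5112 genes.

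Of 37 gene lists fixed before the data were examined, camera called 9, 3 towards higher and 6 towards lower values in Lat. Cholesterol synthesis fell: 16 of 22 members were lower and 0 higher (16 adjusted over the list alone; camera adjusted p = 0.000662, and adjusted p = 0.802 with an estimated correlation). The sterol sensor INSIG1, a member of this list, fell 2.85-fold. It stood at 163 in S-BM 2 against 65.2 to 74.5 in the other S-BM libraries. Over the alternatives its log2 fold change ran from −1.86 to −1.21. In fatty acid oxidation 13 of 24 members fell and 2 rose (15 over the list alone; camera adjusted p = 0.0258, adjusted p = 0.596 with an estimated correlation), among them the acetyltransferase CRAT (2.82-fold lower) and SLC27A2 (2.38-fold lower). Luminal epithelium genes fell in 16 of 21 cases and rose in 2 (19 over the list alone; camera adjusted p = 0.000318, adjusted p = 0.318 with an estimated correlation); the mucin MUC1 went from 45.6 ± 13.99 to 2.51 ± 0.283 and AGR2 fell 5.03-fold. All 8 tested NOTCH pathway genes fell (8 over the list alone; camera adjusted p = 0.00161, adjusted p = 0.17 with an estimated correlation), with the receptor NOTCH3 5.21-fold and the glycosyltransferase LFNG 3.41-fold lower.

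Genes for interferon response and antigen presentation also moved down. Among interferon-stimulated genes 18 of 26 fell and 3 rose (22 over the list alone; camera adjusted p = 0.0031, adjusted p = 0.802 with an estimated correlation); SAMD9L fell 5.14-fold, whereas HERC5, a ligase for ISG15, rose 16.3-fold. Antigen presentation had 10 of 13 members lower and 1 higher (12 over the list alone; camera adjusted p = 0.00161, adjusted p = 0.46 with an estimated correlation). Tapasin (TAPBP) went from 504.5 ± 29.3 to 214.4 ± 4.21.

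The lists that rose concerned growth and stress. MYC targets and ribosome biogenesis had 21 of 29 members higher and 0 lower (22 over the list alone; camera adjusted p = 0.000318, adjusted p = 0.802 with an estimated correlation), including ornithine decarboxylase ODC1 (2.16-fold) and the ribosome assembly factor PES1 (2.03-fold). Proliferation had 22 of 40 higher and 4 lower (26 over the list alone; camera adjusted p = 0.00486, adjusted p = 0.832 with an estimated correlation), with the helicase subunit MCM2 at 29.7 ± 1.53 in S-BM and 87.4 ± 10.8 in Lat and RRM2 2.39-fold higher. For targets of the integrated stress response, 16 of 28 rose and 4 fell (20 over the list alone; camera adjusted p = 0.0368, adjusted p = 0.832 with an estimated correlation). STC2 rose 4.97-fold and NUPR1 fell 4.19-fold; this call ended without S-BM 2 (camera adjusted p = 0.0868) or Lat 4 (0.0967). No list call held with an estimated correlation in any comparison, and 15 of the 35 splits of these 8 libraries gave 9 or more called lists, so the list calls describe directions within these samples.

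Among 14 genes named in advance for metabolism, HER2 and dissemination, of which SOX2 was not tested, 8 passed the test in Lat against S-BM. That count is near the share of all genes tested that passed, 59.7%. The cystine transporter SLC7A11 rose 3.63-fold (130.9 ± 44.4 to 467.8 ± 95.9, adjusted p = 6.19e-06) and the mitochondrial fission GTPase DNM1L 2.15-fold (66.5 ± 4.44 to 144.4 ± 9.75, 3.42e-07). CPT1A, the gate of mitochondrial fatty acid import, rose 1.4-fold (0.00948), the transcription factor SOX9 1.84-fold (2.95e-05) and the adhesion molecule L1CAM 2.64-fold (0.00138). E-cadherin (CDH1) fell 1.92-fold (2.19e-05) and the WNT inhibitor DKK1 1.68-fold (0.00767); the DKK1 call ended when S-BM 3 and S-BM 4 were left out (log2 fold change −0.45, adjusted p = 0.125). The glucose transporter SLC2A1 (log2 fold change 0.04, adjusted p = 0.815), LDHA (0.23, 0.128), the lactate exporter SLC16A3 (0.05, 0.905) and vimentin (VIM; −0.60, 0.416) did not pass. SLC16A3 passed without Lat 3 (0.49, adjusted p = 0.00509), where it was at 20.1 against 64.2 to 75.5 in the other Lat libraries, and LDHA passed without S-BM 3 and S-BM 4 (0.42, adjusted p = 0.0158). Without Lat 3, VIM was at −1.21 (adjusted p = 0.0572). SOX2 was below the filter, at 4.81 ± 4.42 in S-BM, 0.388 ± 0.16 in Lat and 0.593 ± 0.495 in M-BM.

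**Figure D3:**
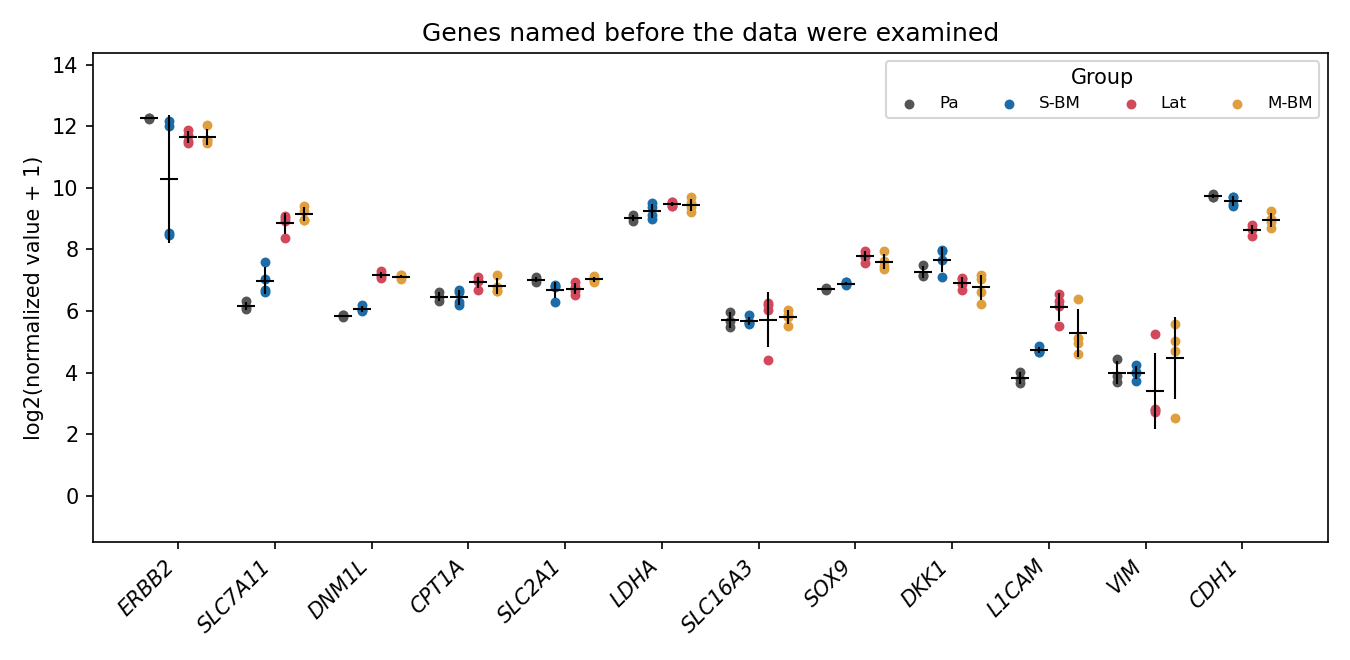
Normalized values on the log2(value + 1) axis for genes named in advance that passed the filter; points are libraries, bars are the mean ± SD of the log2 values (n = 4, Pa n = 3), and Pa is drawn as deposited in its own table. DNM1L and SLC7A11 are higher in Lat and M-BM than in S-BM, and ERBB2 falls to 353 and 367 in S-BM 3 and S-BM 4 only.

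ERBB2, which encodes HER2 (chromosome 17, 39688094 to 39728658), differed more within S-BM than between groups. It stood at 4109 and 4642 in S-BM 1 and S-BM 2 and at 353 and 367 in S-BM 3 and S-BM 4, against 3225 ± 427 in Lat, 3243 ± 634 in M-BM and 4942 ± 26.9 in Pa (n = 3, scaled). It did not pass the test for Lat (log2 fold change 1.35, adjusted p = 0.108) or for M-BM against S-BM (1.35, 0.117). Leaving out S-BM 1 gave 1.92 with adjusted p = 0.0247 for Lat and 1.92 with 0.0286 for M-BM, and leaving out S-BM 2 gave 1.98 with 0.0155 and 1.98 with 0.0183. With S-BM 3 and S-BM 4 left out, libraries chosen by these very values, the direction turned to −0.45 (adjusted p = 0.0418) for Lat and −0.45 (0.0466) for M-BM. A run of 11 neighbouring genes, PPP1R1B to ORMDL3 (chromosome 17, 39626707 to 39927601), was at least 4-fold below Pa in S-BM 3 and S-BM 4; the median log2 ratio to Pa was −3.61 and −3.39 there and −0.16 and −0.01 in S-BM 1 and S-BM 2. CDK12 on one side and PSMD3 on the other lay outside this run, and 9 genes elsewhere on chromosome 17 were as low. The HER2 amplicon list had 4 of 8 tested members higher in Lat than in S-BM and 0 lower (4 over the list alone; camera adjusted p = 0.0607, adjusted p = 0.832 with an estimated correlation), and it was called without S-BM 1 or without S-BM 2.

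**Figure D4:**
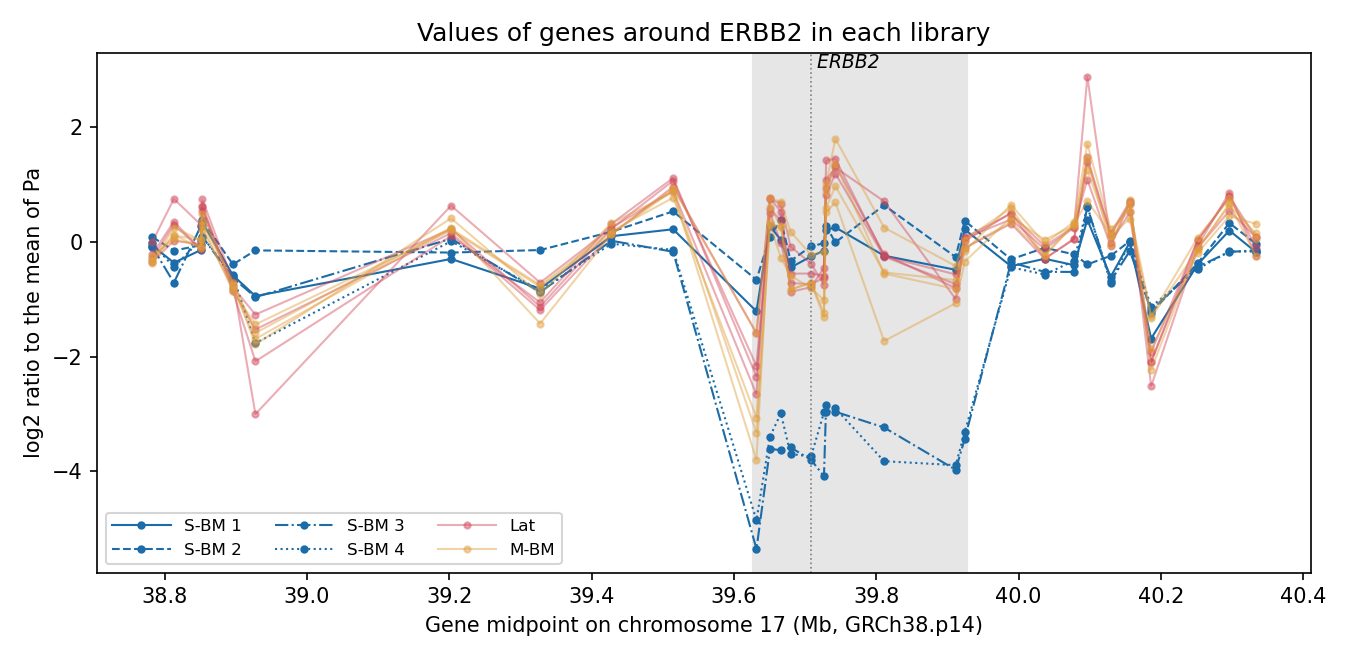
Log2 ratio of each library to the mean of Pa for detected genes around ERBB2, placed by gene midpoint on chromosome 17 (megabases, GRCh38.p14); each line is a library and the shaded run spans PPP1R1B to ORMDL3. In S-BM 3 and S-BM 4 the 11 genes of the run have a median of −3.61 and −3.39, and the 20 flanking genes −0.27 and −0.25.

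M-BM cells against S-BM cells compares cultured cells from metachronous metastases with those from synchronous ones. SPARC, a matrix-associated glycoprotein, rose 72.9-fold, from 0.499 ± 0.377 to 114 ± 51.8 (log2 fold change 6.19, SE 0.63, adjusted p = 6.75e-06). FAM129A rose 42.6-fold, IL24 30.6-fold (to 118 ± 55.4), CES1 29.8-fold and the interleukin 1 receptor family member IL1RAPL1 23.9-fold. The linker histone gene HIST1H1B fell 50.3-fold, RARRES1 24.6-fold, KRT6A 15.4-fold, CP 15.3-fold and TNFSF10 15-fold. LMAN1 was at 0 in M-BM 1, M-BM 2 and M-BM 3 and at 26.8 in M-BM 4, against 100.6 ± 12.2 in S-BM. Adjusted p-values of these 11 genes ranged up to 0.000372. Histone genes have near-identical copies, so the level of HIST1H1B is uncertain. The list of replication-dependent histones did not share its fall, with 2 of 9 tested members higher and 0 lower (camera adjusted p = 0.421). Over the alternatives the log2 fold change ran from 3.75 to 7.81 for SPARC, 3.15 to 6.81 for FAM129A, 3.42 to 5.37 for IL24, 2.67 to 5.36 for IL1RAPL1 and −6.96 to −3.49 for HIST1H1B. Without S-BM 3 and S-BM 4, CES1 went from 4.90 to 3.96 and KRT6A from −3.94 to −3.15. Single libraries moved some of these folds: without M-BM 4 the log2 fold change went from −5.65 to −6.92 for HIST1H1B and from −4.62 to −5.52 for RARRES1, and without M-BM 3 it went from −3.94 to −3.30 for CP. In all, 5084 genes (52.7%) passed, 2597 higher and 2487 lower, and 941 of them changed 2-fold or more (409 higher, 532 lower). The groups did not overlap for 46.2% of genes; leaving out S-BM 3 and S-BM 4 gave 4409 genes.

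Camera called 9 lists in M-BM against S-BM, 4 towards higher and 5 towards lower values, again none with an estimated correlation; 13 of the 35 splits of these libraries gave as many. Cholesterol synthesis had 13 of 22 members lower and 0 higher (14 over the list alone; camera adjusted p = 0.000537, adjusted p = 0.722 with an estimated correlation), with lanosterol synthase LSS 2.49-fold lower. Luminal epithelium had 14 of 21 lower and 1 higher (15 over the list alone; camera adjusted p = 0.000537, adjusted p = 0.304 with an estimated correlation): MUC1 fell 9.38-fold (log2 fold change −3.23, and −3.86 without M-BM 4) and the transcription factor SPDEF 3.42-fold. NOTCH pathway genes fell in 7 of 8 cases (7 over the list alone; camera adjusted p = 0.00203, adjusted p = 0.23 with an estimated correlation), NOTCH3 3.64-fold and the coactivator MAML2 2.99-fold. Interferon-stimulated genes had 18 of 26 lower and 2 higher (21 over the list alone; camera adjusted p = 0.000537, adjusted p = 0.722 with an estimated correlation), with SAMD9L 4.99-fold lower and HERC5 18.2-fold higher. Antigen presentation had 11 of 13 lower and 1 higher (12 over the list alone; camera adjusted p = 0.000537, adjusted p = 0.304 with an estimated correlation), with TAPBP 2.27-fold lower.

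Integrated stress response targets had 18 of 28 members higher and 3 lower (21 over the list alone; camera adjusted p = 0.00203, adjusted p = 0.722 with an estimated correlation); SLC7A11 rose 4.48-fold and STC2 4.11-fold. MYC targets and ribosome biogenesis had 21 of 29 higher and 0 lower (23 over the list alone; camera adjusted p = 8.26e-05, adjusted p = 0.722 with an estimated correlation), with ODC1 2.19-fold and PES1 1.86-fold higher. Proliferation had 20 of 40 higher and 4 lower (24 over the list alone; camera adjusted p = 0.00568, adjusted p = 0.782 with an estimated correlation), with MCM2 2.69-fold and cyclin A2 (CCNA2) 1.97-fold higher; that call ended without S-BM 3 and S-BM 4 (camera adjusted p = 0.0769). The HER2 amplicon list had 4 of 8 higher and 0 lower (4 over the list alone; camera adjusted p = 0.0384, adjusted p = 0.782 with an estimated correlation). GRB7 was at 755 ± 692 in S-BM and 2967 ± 1007 in M-BM (log2 fold change 2.61, adjusted p = 0.00268), and STARD3 at 368 ± 365 and 854 ± 135.5 (2.14, 0.0202). This list lost its call without S-BM 3 (camera adjusted p = 0.0848), S-BM 4 (0.0925) or M-BM 2 (0.0587). With S-BM 3 and S-BM 4 both left out its median log2 fold change went from 1.43 to 0.20 (camera adjusted p = 0.53), GRB7 went to 1.08 and stayed called (adjusted p = 0.00297), and STARD3 went to 0.31 (0.0961). STARD3 lost its call without S-BM 3 (adjusted p = 0.0639) or S-BM 4 (0.0647), and with edgeR (0.133) and DESeq2 (0.161).

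Of the genes named in advance, DNM1L rose 2.06-fold in M-BM against S-BM (adjusted p = 8.71e-07) and SOX9 1.64-fold (0.000248), while DKK1 fell 1.88-fold (0.00282) and CDH1 1.54-fold (0.000803). DKK1 was not called with S-BM 3 and S-BM 4 left out (log2 fold change −0.61, adjusted p = 0.0509). CPT1A (1.29-fold, 0.0451) and SLC2A1 (1.27-fold, 0.031) passed narrowly. CPT1A lost its call without S-BM 1 (adjusted p = 0.111), S-BM 2 (0.125), M-BM 2 (0.143) or M-BM 3 (0.073). Its call also ended with quantile normalization (adjusted p = 0.0557), without a filter (0.0681) and with only these groups in the fit (0.065). The same held with edgeR (0.0549) and with the replicate block (0.0638). SLC2A1 lost its call without S-BM 2 (log2 fold change 0.22, adjusted p = 0.0852), M-BM 1 (0.0562) or M-BM 3 (0.0833). LDHA (log2 fold change 0.19, adjusted p = 0.216), SLC16A3 (0.13, 0.756), VIM (0.47, 0.539) and L1CAM (0.55, 0.149) did not pass. VIM was at 1.11 without M-BM 2 (adjusted p = 0.0781). L1CAM passed without M-BM 4 (0.77, adjusted p = 0.0458), and LDHA without S-BM 3 and S-BM 4 (0.38, adjusted p = 0.0291).

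The changes of Lat and M-BM against S-BM ran in parallel. Both comparisons called 2389 genes higher and 2287 lower, where independent lists would share 785 and 731, and 1 gene was called in opposite directions. Log2 fold changes correlated across genes at 0.961 with a covariance of 0.526. Because both comparisons use the same S-BM libraries, all 12 libraries were simulated 100 times around the S-BM means with no difference between groups. Their comparisons, which share simulated S-BM libraries, gave a mean correlation of 0.5 and a mean covariance of 0.0154. The difference of the covariances was 0.511. The simulations gave 0 shared calls, which follows from drawing no difference. That 0 does not measure how far shared libraries add to shared calls. With separate S-BM libraries for each comparison, in all 6 ways of splitting them, the shared calls were 1652 to 1822 higher and 1587 to 1739 lower, the correlation was 0.831 to 0.938 and the covariance 0.486 to 0.521. Calls in opposite directions numbered 24 with S-BM 1 and S-BM 2 for Lat, 42 with S-BM 3 and S-BM 4 for Lat and 1 in each of the other 4 splits. Those 4 splits parted S-BM 3 from S-BM 4, the closest pair. If this pair is 1 culture, the comparisons were not fully separate there. With the pair kept together the correlations were 0.852 and 0.831.

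M-BM cells against Lat cells compares cultured cells from metachronous metastases with those of the latent group, and here few genes passed the test. FAT2, an atypical cadherin, rose 6.6-fold, from 9.21 ± 3.41 in Lat to 66.4 ± 23.25 in M-BM (log2 fold change 2.72, SE 0.26, adjusted p = 0.000429). SPARC rose from 12.5 ± 19.6 to 114 ± 51.8 (3.96, SE 0.63, 0.027), with Lat 3 at 41.9 and the other Lat libraries at 2.22 to 3.07; without Lat 3 the log2 fold change was 4.84 (adjusted p = 2.66e-06). The fucosidase FUCA2 rose 2.04-fold (0.023). Several calls lay outside the rule for named genes and were chosen after their values were seen. The transcription factor KLF13 rose from 5.78 ± 3.42 to 28.8 ± 2.5 (log2 fold change 2.25, adjusted p = 0.00123). Smooth muscle actin ACTG2 fell from 44.4 ± 6.79 to 5.57 ± 2.56 (−2.87, 0.00244), and the other genes that fell were COL15A1 (−1.49, 0.0343), GALNT6 (−0.85, 0.0306), MGME1 (−0.60, 0.0323) and POLR3F (−0.67, 0.0449). In total 14 genes passed, 9 higher and 5 lower in M-BM, 10 of them at 2-fold or more, and 1049 had an unadjusted p under 0.05. With no difference between groups 482 would do so. The groups did not overlap for 7.3% of genes, where chance gives 2.86% if all libraries are independent. If Lat 1 and Lat 2 are repeats of 1 culture, chance gives more. Leave-outs moved the count widely: 3 genes were called without Lat 1, Lat 2 or M-BM 4, 6 without M-BM 3 and 30 without M-BM 1, and DESeq2 on recovered reads called 141 while edgeR called 12.

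Each of SPARC, FUCA2, COL15A1, GALNT6, MGME1 and POLR3F lost its M-BM against Lat call in some settings: in 12, 6, 11, 8, 8 and 12 of 20 alternatives, in that order, with highest adjusted p-values of 0.181, 0.113, 0.122, 0.108, 0.139 and 0.174. Without Lat 1 the adjusted p was 0.115 for SPARC, 0.0869 for FUCA2, 0.122 for COL15A1, 0.0843 for GALNT6, 0.122 for MGME1 and 0.122 for POLR3F; without Lat 2 it was 0.117, 0.113, 0.117, 0.0873, 0.139 and 0.139. FAT2, KLF13 and ACTG2 passed in every alternative that tested them. None of the genes named in advance passed: ERBB2 had a log2 fold change of 0.00 (adjusted p = 1), SLC7A11 0.30 (0.646), SLC2A1 0.31 (0.38), CDH1 0.31 (0.366), VIM 1.06 (0.554) and L1CAM −0.86 (0.324). VIM was at 1.68 without Lat 3 (adjusted p = 0.275) and 1.71 without M-BM 2 (0.23). L1CAM passed without M-BM 2 (−1.23, adjusted p = 0.0481), where it was at 83.7 against 23.1 to 34.1 in the other M-BM libraries. Camera called 7 lists with 0 members called in any of them (adjusted over the list alone, 1 in glycolysis, 2 in TGF-beta response and 2 in YAP and TEAD targets): glycolysis (adjusted p = 0.0062), fatty acid oxidation (0.0161), luminal epithelium (0.0381), NOTCH pathway (0.0381) and cytosolic ribosomal proteins (0.0381) towards higher values, and YAP and TEAD targets (0.0256) and TGF-beta response (0.0381) towards lower values. With an estimated correlation the adjusted p of these lists was 0.472 to 0.688, and 15 of the 35 splits gave 7 or more lists.

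Pa stands in a separate table, and whether it was normalized together with the other libraries is not given in the sources used here, so it was set beside the other groups as levels only, scaled by the median ratio of 1.0062, with no test. Among 9907 genes, 17 lay at least 4-fold outside the range of all 12 brain-derived libraries. Pa was higher for 11 of them, including the keratins KRT13 (179 ± 97.4, n = 3, against 1.29 to 19.1) and KRT4 (134 ± 35.5 against 0 to 20.6), the antiviral gene OAS2 (83.2 ± 23.8 against 0.07 to 10.2) and CEACAM5 (82.0 ± 17.1 against 0.1 to 6.38). It was lower for 6, including CD109 (1.85 ± 0.3 against 24.4 to 126.8), GFPT2 and the collagen IV chains COL4A1 and COL4A2. These names were chosen after their values were seen. By group, S-BM had 7 genes with all its libraries at least 4-fold above every Pa library and 17 below, Lat 104 and 253, and M-BM 73 and 140. Since all libraries of a group must lie outside, 1 library near Pa lowers its count. M-BM 4 correlated with Pa libraries at 0.867 to 0.88, and the other M-BM libraries at 0.807 to 0.837. For luminal epithelium the median log2 difference from Pa was −0.39 in S-BM, −1.29 in Lat and −1.22 in M-BM, and for MYC targets and ribosome biogenesis it was 0.43, 0.97 and 0.99. Where Pa differs from the brain-derived libraries, table and group cannot be told apart.

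Markers of other brain cell types were mostly below the filter and too few to test. Of the matched markers, 3 of 23 synapse and neuronal genes passed the filter (highest value 63.7, TUBB3 in S-BM 3), 3 of 10 astrocyte markers (425.3, SLC1A3 in Pa 3), 2 of 10 oligodendrocyte markers (211, CNP in Pa 3), 2 of 10 microglia and other immune markers (30.9, CD68 in Lat 3) and 0 of 13 endothelial and pericyte markers (17.7, CDH5 in Pa 2). For astrocyte, oligodendrocyte and endothelial markers the highest value was thus in a parental library. Metallothioneins had 3 of 9 members past the filter, with MT2A highest at 658 in S-BM 3.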

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

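Among the tests in this part, those of library scaling for S-BM, of depth for M-BM 4, of a short segment on chromosome 17, of quantile normalization and of the wider share estimate were chosen after the results were seen. The tests of another cell line, of the strict share estimate and of neighbouring genes, and all regroupings of the libraries, were set before.

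ERBB2 and its neighbours stood low in S-BM 3 and S-BM 4. Library scaling is argued against, since it would lower neighbouring genes alike: the median log2 ratio to Pa over the 20 nearest detected genes outside the run was −0.27 in S-BM 3 (quartiles −0.64 and −0.06) and −0.25 in S-BM 4, against −3.61 and −3.39 in the run. Cells of another line are argued against as well: 0 genes stood at 10 or more in both libraries and under 1 in the other 13. A change confined to a short segment of 17q12, such as a loss of amplified copies in these cells, may be a candidate explanation. Of the 20 nearest detected genes outside the 11-gene run 0 were as low, although 9 genes elsewhere on chromosome 17 were. The run was extended from ERBB2 until a gene was not as low, so the nearest gene on each side could not be as low. PPP1R1B at its edge was also below Pa in Lat (log2 ratio −2.66 to −1.60) and M-BM (−3.80 to −1.59). DNA was not measured, the labels give no difference between these libraries, and no biological explanation from the design was tested.

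M-BM 4 lay between S-BM and the other M-BM libraries on the first component, with LMAN1 at 26.8 against 0 in the other M-BM libraries, RARRES1 at 116 against 4.48 to 17.8, MUC1 at 16.7 against 1.94 to 2.26, HIST1H1B at 35.1 against 0 to 0.195 and SLC27A2 at 22.5 against 15.6 to 16.7. Its depth of 21.08 M reads lay inside the range of the other libraries, which argues against depth. A share of S-BM-like cells in M-BM 4 could give such values. The strict test rests on a single gene per side, and the 2 estimates of the share differ by 0.19, which leaves it open. Over 49 genes lower and 38 genes higher in Lat than in S-BM by 8-fold or more, the median shares were 0.167 and 0.205. Their difference of 0.038 is under a bound of 0.1, which was set after the result was seen. The quartiles on the higher side were 0.006 and 0.363. For the other M-BM libraries, each set against the remaining M-BM libraries, the estimates ran from −0.195 to 0.108. M-BM 2, at −0.058 and −0.076, also had medians close to each other. Those references contained M-BM 4, so these values depend on it and are no separate control. Closeness of the 2 medians alone cannot show a share of S-BM-like cells. Cells intermediate between the groups would give like values, and no biological explanation from the design was tested.

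Lat and M-BM differed from S-BM at over 50% of the genes. Library scaling is argued against, since quantile normalization gave 5760 genes for Lat against S-BM where the values as deposited gave 5754. Neighbouring genes moved together: the SD of medians over 180 windows of 50 genes was 0.276 for Lat against S-BM, above the highest of 1000 shuffled orders, 0.118. Part of the difference may therefore follow chromosomal segments, as a selected subclone with other copy numbers would give, but regulation over domains would do the same and M-BM against Lat showed a like ratio to its shuffled orders (2.9 against 2.77). The groups themselves remain an open, untested biological explanation.

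Regroupings of the libraries were set beside the real grouping. Where groups truly differ, a mixed split moves that difference into the spread within groups and lowers its count. The low gene counts of the other splits are therefore not a chance level. For Lat against S-BM, 1 of 35 splits, the real one, reached 5754 genes (highest other 2) and 1 of 35 reached 1294 genes at 2-fold (highest other 1). For M-BM against S-BM, 1 of 35 reached 5084 genes (highest other 3) and 941 at 2-fold (highest other 2). For M-BM against Lat, 1 of 35 reached 14 genes (highest other 7) and 10 at 2-fold (highest other 6). For each of these 6 counts, as fitted with all libraries, only the real split reached the count. This is the smallest share that 35 splits can give. The splits take the libraries as independent, which the labels do not state. S-BM 3 and S-BM 4 stood at 2.17 times the noise level and Lat 1 and Lat 2 at 2.64 times. The counts thus follow the real grouping in these libraries, but the splits do not exclude chance. The counts for M-BM against Lat are also fragile. They were 3 genes without Lat 1, Lat 2 or M-BM 4, 6 without M-BM 3 and 30 without M-BM 1. Fitting only these groups gave 5. For called lists chance is not excluded either, and splits that exchange 1 library keep part of any real contrast. Of the 35 splits, 15 reached the 9 lists of Lat against S-BM (highest other 13). The 9 lists of M-BM against S-BM were reached by 13 (highest other 12), and the 7 of M-BM against Lat by 15 (highest other 14). For a difference among any of the 3 groups, 1 of 100 drawn groupings reached 5477 genes, with 5144 in the highest other. That grouping kept the 4 S-BM libraries together and mixed Lat with M-BM, and the other 98 drawn groupings, which parted S-BM, gave 0 to 3 genes, so the large count points to a structure of the samples, S-BM against the rest.

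Further values lay far from the other 3 libraries of their group; 21 of 195 groups of values did so, 7 of them in Lat 3 and 5 in M-BM 4. Chance gives about 1 in 20 for independent values, but these genes were picked for large changes or for their lists and share libraries, so that rate was not shown to hold here. In Lat 3, KRT6A was at 4.92 against 0.616 to 0.976, VIM at 37 against 5.65 to 6.06 and SCD at 120 against 317 to 332. Also in Lat 3, FN1 was at 4950 against 1790 to 1940, SPARC at 41.9 against 2.22 to 3.07, SPDEF at 9.16 against 10.7 to 10.8 and KLF13 at 10.9 against 3.49 to 4.62. In S-BM 2, INSIG1 was at 163 against 65.2 to 74.5, NOTCH3 at 115 against 67 to 74.1, SLC2A1 at 78.2 against 108 to 113 and SPARC at 1.06 against 0.285 to 0.349. In M-BM 2, LFNG was at 21.4 against 9.8 to 11.4 and ERBB2 at 4180 against 2800 to 3000. Single values were ABCG2 in M-BM 3 (74.5 against 54.7 to 57.3), TAPBP in Lat 2 (221 against 212 to 213) and FADS1 in Lat 4 (55.4 against 46.2 to 46.8).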

How the results depend on the processing

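The filter at a value of 1 and leaving out S-BM 3 and S-BM 4 together were chosen after the data were seen; all other alternatives were planned. Counts of called genes for Lat against S-BM and M-BM against S-BM stayed within 1.5 times 5754 and 5084 under each alternative except the filter at 100, with 5176 to 5545 and 4383 to 4889 when single libraries were left out. Of all values for summary counts 160 stayed and 49 moved; of those for named genes and lists 3015 kept their direction and side of the threshold, 141 lost a call, 9 gained one and 21 changed direction. Unless stated, the cause of a change was not tested.

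A pseudocount of 8 gave 816, 531 and 6 genes at 2-fold for Lat against S-BM, M-BM against S-BM and M-BM against Lat, since it shrinks folds of low values. Over the alternatives the log2 fold change for Lat against S-BM ran from −6.145 to −3.493 for TNFSF10, −5.108 to −3.693 for CP, −4.938 to −3.784 for RARRES3, 2.969 to 4.398 for ABCG2, 2.254 to 4.661 for HERC5 and −4.188 to −2.315 for MUC1. For M-BM against S-BM it ran from −4.414 to −2.894 for TNFSF10, −4.458 to −3.106 for CP, −5.519 to −3.627 for RARRES1, −4.474 to −2.688 for KRT6A, 2.805 to 6.003 for CES1 and 2.383 to 4.795 for HERC5, and for M-BM against Lat from 2.858 to 4.836 for SPARC, 1.444 to 2.553 for KLF13 and −3.307 to −1.959 for ACTG2. Without a filter 2-fold counts were 2062 and 1525 for the comparisons with S-BM, and 24 genes were called for M-BM against Lat. The filter at 100 left fewer genes to test and gave 1815 and 308 at 2-fold, 1644 and 207, and 0 and 0, with 1759 for any difference among groups. The filter at 1 gave 2-fold counts of 2039 and 1526, and 26 and 19 genes for M-BM against Lat. For that comparison, fitting only its own libraries gave 5 and 5, DESeq2 141 and 29, and edgeR 12 and 9. With the replicate block, 5675, 5002 and 13 genes were called, 1300, 946 and 9 at 2-fold and 5382 in the F test, with 10, 9 and 8 lists. The block added the HER2 amplicon list for Lat against S-BM and ended the calls of CPT1A for M-BM against S-BM (adjusted p = 0.0638) and of FUCA2 (0.0509) and POLR3F (0.0844) for M-BM against Lat.

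Without single libraries, M-BM against Lat gave 3 (without Lat 1, Lat 2 or M-BM 4) to 30 genes (without M-BM 1), with 3 to 14 at 2-fold, so its count rests on single libraries. Its called lists ranged from 2 (without Lat 2) to 12 (without Lat 4), and were 11 without S-BM 3 and S-BM 4. With an estimated correlation 0, 0 and 0 lists were called, and with fry 20, 21 and 0.

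Correlation of the changes shared by Lat and M-BM, 0.961, fell when each comparison had its own S-BM libraries: 0.852 with S-BM 1 and 2 for Lat, 0.938 with 1 and 3, 0.934 with 1 and 4, 0.931 with 2 and 3, 0.933 with 2 and 4 and 0.831 with 3 and 4. Pa lay outside for 68 genes at 2-fold and for 4 with the filter at 100, and for 20 to 23 without single Pa libraries.

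Directions also turned. Without S-BM 3 and S-BM 4, libraries chosen by these values, ERBB2 was at −0.447 for Lat and −0.448 for M-BM against S-BM, and SLC16A3 at −0.025 for Lat against S-BM. Without single libraries, Lat against S-BM ranged from −0.09 (without S-BM 2; −0.038 without Lat 4) to 0.106 for SLC2A1 and from −0.132 to 0.488 for SLC16A3 (−0.114, −0.055 and −0.132 without Lat 1, 2 and 4). For M-BM against Lat, ERBB2 was at 0.003 with TMM rescaling, 0.07 with quantile normalization and 0 with edgeR, and ranged from −0.13 to 0.077 without single libraries (0.019 and 0.077 without Lat 1 and 4; 0.062, 0.031 and 0.03 without M-BM 1, 3 and 4). SLC16A3 was at −0.077 with edgeR and −0.082 with DESeq2, and ranged from −0.363 (without Lat 3) to 0.257. LDHA ranged from −0.121 to 0.04 (without M-BM 2) and DKK1 from −0.287 to 0.016 (without M-BM 3).

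Depth limits the lowest values: 3 reads stand for 0.136 to 0.225, far under the filter at 10.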

Other observations

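The genes named in this part were chosen after their values were seen, and no explanation is offered.

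Camera did not call 28 of the 37 lists for Lat against S-BM (adjusted p 0.0607 to 0.984). Counts are of members called higher and lower, with those adjusted over the list alone in brackets. Glycolysis had 4 higher and 7 lower of 21 (11; adjusted p = 0.609), hypoxia response 6 and 6 of 17 (12; 0.947), pentose phosphate 2 and 3 of 10 (5; 0.947), the tricarboxylic acid cycle 3 and 10 of 26 (12; 0.41) and oxidative phosphorylation 9 and 13 of 44 (21; 0.532). Glutamine, cystine and glutathione genes had 9 and 6 of 22 (15; 0.461), NRF2 targets 9 and 6 of 24 (15; 0.455), lipid uptake and droplets 3 and 5 of 10 (8; 0.587), mitochondrial fission and fusion 7 and 7 of 18 (14; 0.938) and the unfolded protein response 4 and 8 of 18 (12; 0.532). Fatty acid synthesis and desaturation had 3 and 9 of 15 (12; 0.148): SCD went from 1371 ± 225 in S-BM to 273.6 ± 102.7 in Lat and FADS1 from 2.71 ± 0.908 to 48.7 ± 4.46.

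Among lists of cell state, mesenchymal genes had 7 higher and 3 lower of 15 (10; adjusted p = 0.41), basal epithelium 4 and 10 of 19 (14; 0.257), TGF-beta response 8 and 5 of 20 (13; 0.587), WNT 2 and 2 of 8 (3; 0.897), YAP and TEAD targets 12 and 3 of 22 (15; 0.213) and latency 5 and 6 of 17 (11; 0.984). FN1 rose from 411 ± 96.1 to 2626 ± 1552 and AXL from 70.1 ± 51.2 to 380.9 ± 48.9 (log2 fold change 2.99, with 2.13 without S-BM 2 and 4.23 without S-BM 3 and S-BM 4). ERBB receptors, ligands and feedback had 6 and 2 of 12 (8; 0.213), cell-cycle inhibitors and p53 targets 7 and 7 of 18 (14; 0.947), brain metastasis mediators 5 and 9 of 18 (14; 0.333) and proteases 6 and 8 of 18 (14; 0.587). NK-cell ligands had 5 and 4 of 13 (9; 0.973), NF-kappaB and cytokines 6 and 6 of 16 (12; 0.897), S100 proteins 4 and 4 of 11 (8; 0.938), ribosomal proteins 5 and 14 of 51 (16; 0.235), immediate early and heat shock genes 8 and 3 of 21 (11; 0.472) and histones 5 and 0 of 9 (5; 0.172). Median, mean and test differed in sign for glycolysis (median 0.04, mean −0.11), pentose phosphate, cell-cycle inhibitors and NF-kappaB.

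For M-BM against S-BM 28 lists were not called (adjusted p 0.101 to 0.993), among them fatty acid oxidation with 2 higher and 10 lower of 24 (12; 0.101). In M-BM, SCD was at 377.2 ± 126.6, FADS1 at 48.0 ± 9.12, FN1 at 1468 ± 302 and AXL at 471.6 ± 221 (log2 fold change 3.20 against S-BM, with 2.34 without S-BM 2 and 4.43 without S-BM 3 and S-BM 4). For M-BM against Lat 30 lists were not called (0.0508 to 0.981).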
